A study of Zea mays with 38 samples.

How the data were processed

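Leaves of maize (Zea mays) seedlings of the inbred line B73 were exposed to UV-B or kept as controls, and their total RNA was compared on 2-colour cDNA microarrays at 1, 2, 4, 8 and 12 h. Each slide carried 1 UV sample and 1 control sample of the same time, labelled with Cy5 and Cy3. The samples formed 10 groups, UV and control at each time. Of each time, 4 slides with the replicate letters a to d were used, except that 3 slides (a, c and d) were used at 2 h, and slide b of that time was not analysed here. In all, 19 slides and 38 samples entered the fits. UV was labelled with Cy5 on slides a and b and with Cy3 on slides c and d. Where the source label and the title of a sample gave different replicate letters, the title was used. The labels do not say whether the slides of a time came from separate plants or extracts, so the spread between slides may be technical. The p-values of the main fit measure a spread per feature pooled over the slides of all times, not that of a single time.

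The deposited per-sample files gave one intensity per spot and channel on a linear scale, and per the labels the scanned images were gridded or analysed with TIGR Spotfinder. Whether a local background was subtracted, and which scanner was used, is not given in the sources used here. Each channel held between 18795 and 20158 spots, and the median intensity of a channel ran from 138059 to 626914. The series matrix holds the authors' processed score of the same samples in 19818 rows, whose scale, centring and background treatment were not given in the sources used here. Its column medians lay between 12.24 and 12.35. Its columns correlated with log2 intensity of the same sample at r between 0.748 and 0.827 across features, and its log ratios per slide with those of the intensities at r between 0.690 and 0.845. Its direction therefore matched the intensities, its exact scale stayed unknown, and it was used only as an alternative. No pair of columns held identical values, and 0 columns stayed without a sample.

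Intensities were corrected with the normexp method of limma 3.58.1 (R 4.3.3) with an offset of 50, and log2(UV/control) was normalized within each slide by loess with a span of 0.3. Whether the intensities had already been corrected is unknown, so the uncorrected intensities were an alternative. Counts from uncorrected intensities had been seen before normexp was settled on; the choice followed the rule fixed earlier and not those counts. Of 20231 spot positions, 120 control and other specially named spots were left out of loess and of the tests. Spots of one feature were averaged, which concerned 35 features. A feature was tested when at least 2 slides of every time measured it, which left 20021 of 20083 features. Transgene or foreign sequences on the slides served as a measure of unspecific signal: the brightest of 7 had a mean log2 intensity of 16.76, and 14512 tested features (72.5%) lay above it.

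Features were named by the platform's gene table, which listed 1334 probes. Of these, 1331 had 1 gene symbol and 3 had several, so that 18690 tested features had no or several genes and stayed unnamed here. The symbols stood for 779 genes, and 1283 probes had their gene in the RefSeq gene table. Symbols made only from a locus number were not informative, which left 1168 features of 685 genes. Different features of one gene were kept apart and are given with their identifiers as the files give them.

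The limma model fitted log2(UV/control) of all slides with 5 time means and a dye term, and moderated the variances with eBayes. It had 13 residual degrees of freedom and 2.75 prior degrees of freedom. Contrasts gave the change at each time and the mean over the times, and a moderated F-test compared the UV response at 2, 4, 8 and 12 h with that at 1 h. The control samples were compared over time with the separate-channel fit of limma after Aquantile normalization. The intraspot correlation was 0.786. This fit needs complete values and ran on the 14234 features (71.1%) measured on all slides, a departure from the filter above. All p-values were adjusted by the Benjamini-Hochberg method over the features of a comparison, with a threshold of 0.05. UV and control samples of one slide deviated together from their group means at r between 0.658 and 0.922. Both were read from the same spots, which alone can give such values. They thus speak for a fit paired by slide and do not show that the plants were paired.

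The named features followed a fixed rule. At each time and for the mean over times, it took the 6 largest rises and the 6 largest falls among informative names with an adjusted p under the threshold and the same sign on every slide of that time, or on at least 15 slides for the mean. It added, for each list and time, the 2 passing members with the largest change. Where no feature passed, the 3 higher and the 3 lower features with the smallest p are given as values. Between times, it took the 6 smallest p.

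Gene lists were tested with the camera statistic and a preset correlation of 0.01, with the estimated correlation set to 0 where negative, and with fry on members measured on all slides. The results of fry are not given below. Lists with at least 5 members were tested, and their p-values were adjusted over all lists and contrasts of a family. The first family held 19 lists. It had no members here for cytosolic ribosomal proteins, translation factors, DNA repair, ubiquitin and proteasome, circadian clock, and cuticle. Its other 13 lists, of which 7 were tested, covered flavonoid synthesis, photosynthetic light reactions, mesophyll C4 cycle, bundle sheath carbon fixation, histones and chromatin factors, heat shock proteins and chaperones, antioxidant enzymes, pathogenesis-related and wound proteins, jasmonate and lipid signalling, sugar and starch metabolism, dividing cells, endosperm and seed storage, and root and pollen. The gene table gives symbols and no descriptions for matching, so the first family was matched by symbol alone. The second family held 22 lists built from the symbols on the slides, after the feature names and before any expression value had been seen. The samples, the model, the first family of lists, the named-feature rule and most alternative settings were fixed before the data were examined.

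The scripts were tested on simulated data drawn with a single spread per feature, the same on every slide and independent between features. The real slides differed, with a mean residual SD of 0.43 at 2 h and 0.293 at 12 h. The shares below therefore do not show what the slides of a given time could detect. Among 100 features changed by 1 on the log2 scale, the fit recovered 51% at 1 h, 54% at 2 h, 69% at 4 h, 63% at 8 h, 66% at 12 h and 96% for the mean over times. For changes of 0.5 on the log2 scale, the shares were 23%, 13%, 30%, 21%, 24% and 84% in the same order. For a change of 1, the test between times recovered 44%, and the control time course 29% of 100 changed among 14234 features. The number of slides limits the precision of all comparisons.

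Alternative settings fixed with the model were a fit without the pairing, no dye term, median centring, no background correction, a filter on dim features, a filter on missing values, the series matrix, a fit to the slides of one time alone, an intensity trend with robust variances, slide weights, scaling between slides, and leaving out each slide. Those chosen after seeing the data were loess within each of 48 blocks of spots, a filter at the brightest foreign spot, and an offset of 50 without normexp. The fit to the slides of one time alone had no dye term. The refits of the control time course without a slide, with slide weights or with trend and robust variances kept the intraspot correlation of all slides.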

Results

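Transcript levels in leaves of maize seedlings (inbred B73) under UV-B radiation were compared with those of control plants on 2-colour cDNA microarrays. A control group at every time separated the response to UV from changes over the day. Slides were measured at 1, 2, 4, 8 and 12 h of irradiation, 4 per time and 3 at 2 h, each with 1 UV and 1 control sample, which gave 19 slides, 38 samples and 10 groups. A channel held 18795 to 20158 spots with a median intensity of 138059 to 626914. By time, the channel medians ran from 138059 to 340785 at 1 h, from 143739 to 396176 at 2 h, from 236225 to 490613 at 4 h, from 258114 to 477212 at 8 h and from 348208 to 626914 at 12 h. All changes are log2(UV/control) ± SE from the limma fit to all slides, and n is the number of slides. The SE rests on a spread per feature pooled over all times, so it does not measure the spread of the slides of that time alone. At 8 h, for example, a chitinase feature ran from 0.88 to 4.22 over its 4 slides, beside an SE of 0.43.

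The first comparison asked which transcripts differed between UV and control leaves on average over the 5 times. UV-treated leaves had more transcript of a catalase, which breaks down hydrogen peroxide (feature AI999974, 1.10 ± 0.12, n = 19, adjusted p = 0.000143, higher on 15 slides), and of the peroxidase PER42 (0.73 ± 0.083, n = 19, adjusted p = 0.000143, higher on 16). Some chaperones and folding enzymes of the endoplasmic reticulum rose with them. The calreticulin crt2 rose by 0.73 ± 0.13 (n = 18, adjusted p = 0.00206, 15 slides), the protein disulfide isomerase pdi2 by 0.64 ± 0.10 (n = 19, adjusted p = 0.000821, 16 slides), and the calnexin CNX by 0.60 ± 0.092 in one feature and 0.54 ± 0.075 in another (adjusted p = 0.000651 and 0.000387, 17 slides each). The third CNX feature (AW257966) stood the other way, at -0.25 ± 0.15 (adjusted p = 0.301). The cellulose synthase gene CesA-9 fell by 0.47 ± 0.075 (n = 19, adjusted p = 0.000883, lower on 18 slides). The naming rule required one direction on at least 15 slides, so the slide counts of the named features are not separate evidence.

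Other falls in the mean over times included genes of photosynthesis. The gene gpa1, for a chloroplast glyceraldehyde-3-phosphate dehydrogenase subunit, changed by -0.45 ± 0.090 (adjusted p = 0.00389, lower on 16 slides), and Lhcb5-2, for a light-harvesting protein, by -0.39 ± 0.075 (adjusted p = 0.00301, 15 slides). The MADS-box gene m16 changed by -0.46 ± 0.10 (adjusted p = 0.00756, 16 slides), pOMT1 by -0.44 ± 0.085 (adjusted p = 0.00277, 16 slides) and the starch synthase gene ss2 by -0.38 ± 0.095 (n = 18, adjusted p = 0.0157, 15 slides). Of 20021 features tested, 2884 passed, of which 1746 rose and 1138 fell. The 11 named features other than ss2 passed in all settings that kept the pairing, and ss2 was lost with the matrix values (or with loess within blocks of spots). The count fell to 132 when the pairing by slide was ignored.

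**Figure D1:**
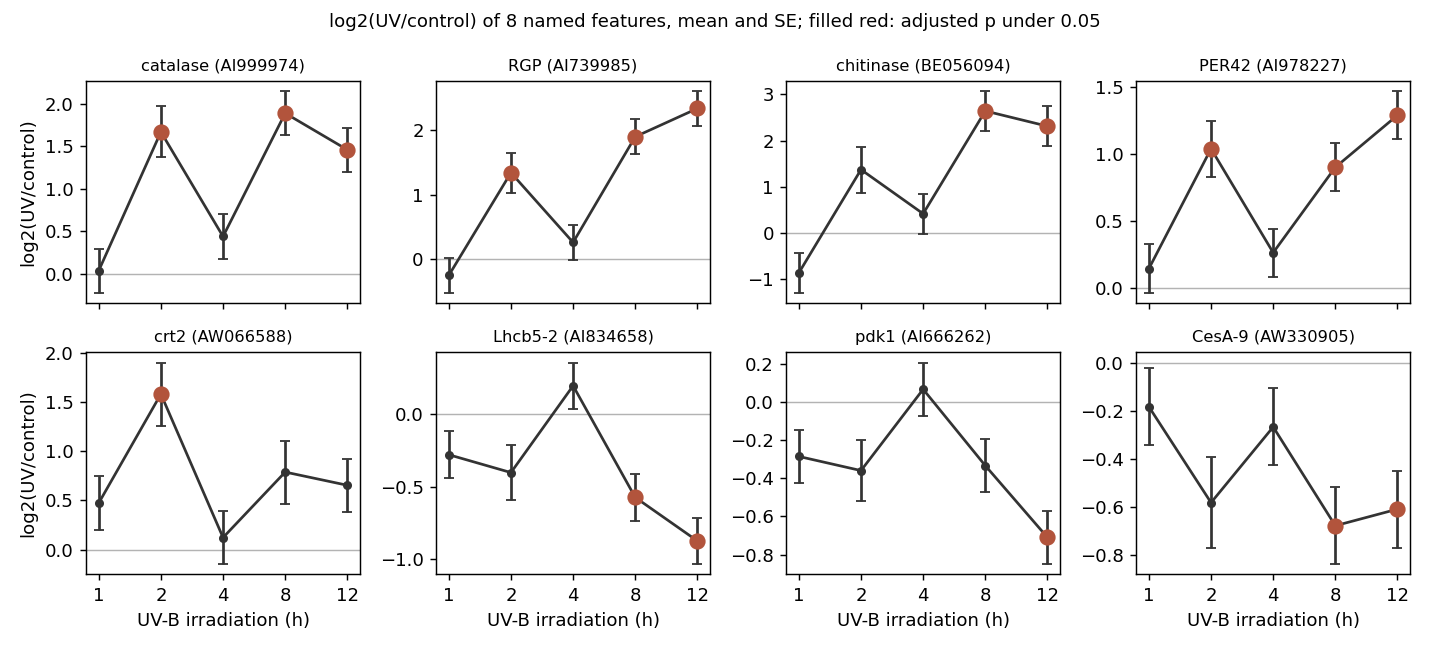
Log2(UV/control) (vertical axes, log2 units) against the duration of UV-B in h (horizontal axes, evenly spaced) for 8 named features. Points are changes from the limma fit with its dye term (3 or 4 slides per time), and bars are their SE. Points in red had an adjusted p under 0.05. Chitinase reached 2.64 at 8 h and RGP 2.34 at 12 h, while Lhcb5-2 stood at -0.87 at 12 h.

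At 2 h, the largest rises were those of the catalase (1.67 ± 0.30, n = 3, 3.18-fold, adjusted p = 0.0118), crt2 (1.58 ± 0.32, adjusted p = 0.0181) and tacs1 (1.5 ± 0.26, adjusted p = 0.0103). The acidic ribosomal protein gene arpp2a (BU093490, 1.42 ± 0.18, adjusted p = 0.00423), RGP, named for a reversibly glycosylated polypeptide (1.34 ± 0.31, adjusted p = 0.0288), and the elongation factor gene elfa5 (1.33 ± 0.28, adjusted p = 0.022) followed. The GTPase gene ypt1 fell by 1.21 ± 0.30 (adjusted p = 0.0389), m16 by 1.14 ± 0.26 (adjusted p = 0.0265), and the aquaporin gene PIP1-3 by 1.00 ± 0.22 in feature AI947544 (adjusted p = 0.0255). Smaller falls were those of pOMT1 (-0.79 ± 0.21, adjusted p = 0.0489), por (-0.63 ± 0.15, adjusted p = 0.0342) and the methyl-CpG-binding gene mbd111 (-0.52 ± 0.11, adjusted p = 0.0208). Each of these features had one sign on all 3 slides, as the naming rule required.

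Among list members at 2 h, hsp70-4 rose (0.60 ± 0.15, adjusted p = 0.0382) and mn1, a cell wall invertase gene, fell (-0.45 ± 0.12, adjusted p = 0.0473), each on 3 of 3 slides. The features of tacs1, mbd111 and mn1 were dimmer than the brightest foreign spot. The mn1 call was lost in 26 of 30 settings that kept the pairing, where its change ran from -0.599 to -0.042. Of 20021 features, 546 rose and 283 fell at 2 h. The 829 calls became 203 without slide c, 244 without slide a, 43 after scaling between slides, and 0 when the pairing was ignored or the 2 h slides were fitted alone. Of the 14 named results, 3 passed without slide c, where the changes stood at a median of 0.808 of the full value. Without it, ypt1 stood at only -0.621 ± 0.27 (adjusted p = 0.289) and m16 at -0.513 ± 0.15 (adjusted p = 0.117). The calls of RGP, pOMT1, por and mn1 were lost without each of the 3 slides in turn, and pOMT1 lost its call in 22 of 32 settings that kept the pairing. The slides of opposite dye assignment at 2 h correlated at a median r of -0.285 across features.

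At 8 h, a chitinase, an enzyme of defence against fungi, rose most (2.64 ± 0.43, n = 4, 6.24-fold, adjusted p = 0.0064), and RGP (1.90 ± 0.27, adjusted p = 0.00462), the catalase (1.89 ± 0.26, adjusted p = 0.00462) and lls1, named for the lethal leaf spot phenotype (1.35 ± 0.20, adjusted p = 0.00522), rose with it. Further rises were those of elfa5 (1.28 ± 0.28, n = 3, adjusted p = 0.0158) and the aquaporin gene pip2f (1.19 ± 0.32, adjusted p = 0.0352). The bZIP transcription factor genes GBF1 (-1.12 ± 0.26, adjusted p = 0.0201) and OBF1 (-1.12 ± 0.22, adjusted p = 0.01) fell. The largest fall was that of lop1 (BQ486471, -1.42 ± 0.38, n = 3, adjusted p = 0.0342), and 3 of the 9 lop1 features passed, all lower. SE1B (-0.98 ± 0.21, adjusted p = 0.014), ypt1 (-0.94 ± 0.26, adjusted p = 0.04) and ZCAX2 (-0.90 ± 0.16, adjusted p = 0.00706) also fell. All of these had one sign on every slide that measured them, as the naming rule required.

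Among list members at 8 h, features for enzymes of jasmonate synthesis went both ways. The allene oxide cyclase gene aoc1 rose by 1.02 ± 0.23 (BQ294408, adjusted p = 0.0179) and the oxophytodienoate reductase gene opr1 by 0.88 ± 0.19 (adjusted p = 0.0126), each on 4 of 4 slides. The aoc1 feature owed much of its change to slide a (2.44, against 0.486 to 0.592 on the others) and stood at 0.529 ± 0.13 without it (adjusted p = 0.0763). The other 6 aoc1 features did not pass, and 2 of them stood at -0.415 and -0.0842. The related gene opr6, chosen after its values were seen, fell by 0.59 ± 0.14 (adjusted p = 0.0207). The sucrose synthase gene sh1 rose in 2 features, by 1.02 ± 0.26 (3 of 3 slides, adjusted p = 0.0283) and 0.88 ± 0.25 (3 of 4 slides, adjusted p = 0.0418). The chromatin gene nfc102 (1.04 ± 0.25, adjusted p = 0.0204), the superoxide dismutase gene sod2 (BQ279929, 0.42 ± 0.12, adjusted p = 0.0401) and the globulin gene glb1 (AW066754, 0.75 ± 0.18, adjusted p = 0.0203) rose, and hsp101 fell (-0.57 ± 0.15, adjusted p = 0.0359), on 4 of 4 slides each. The features of glb1 and hsp101 were dimmer than the brightest foreign spot, and this glb1 feature stood at -0.16 with median centring. The other 2 glb1 features stood at -0.21 and -0.65.

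Of 20021 features, 1012 rose and 498 fell at 8 h. The calls depended on slide a: without it 7 features passed, and none of the 20 named results did. All 20 kept their direction, but the naming rule required one sign on every slide for most of them, so this is not separate evidence. Most of these changes stayed of similar size, at a median of 0.902 of the full value, while their SE grew by a median factor of 1.17. The chitinase stood at 2.27 ± 0.48 (adjusted p = 0.063), RGP at 1.83 ± 0.32 (adjusted p = 0.0509) and opr1 at 0.925 ± 0.23 (adjusted p = 0.0725). Other changes shrank, with lop1 at -0.538 ± 0.21 (adjusted p = 0.223) and sh1 feature AI861486 at 0.398 ± 0.22 (adjusted p = 0.416). The other sh1 feature stood at 0.566 ± 0.25 without slide b (adjusted p = 0.236), and nfc102 at 0.515 ± 0.13 without slide c (adjusted p = 0.0404). The calls of ypt1 and pip2f were lost without each of the 4 slides in turn. The count was 342 without slide b, 772 without slide d, 893 without the dye term, 3183 with median centring (47.3% higher, against 67%), 2723 with slide weights, 986 after scaling, 9 without the pairing and 0 with the 8 h slides alone.

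**Figure D2:**
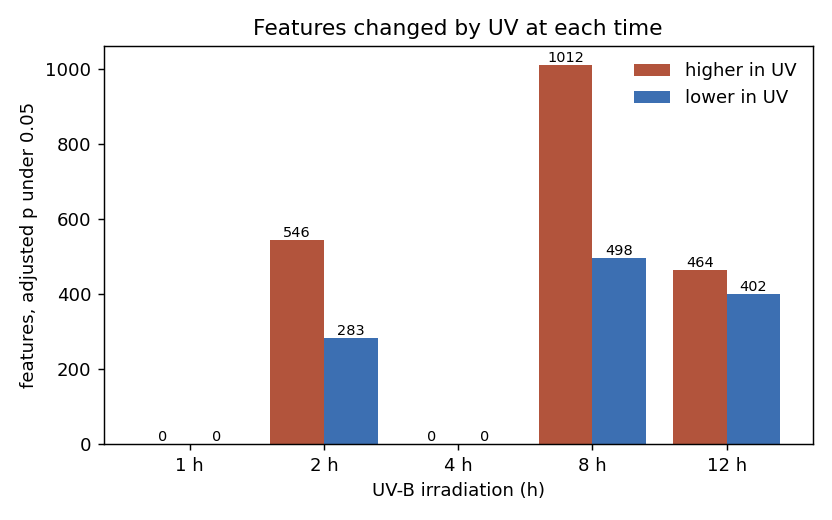
Number of features with an adjusted p under 0.05 (vertical axis) against the duration of UV-B in h (horizontal axis), with features higher in UV in red and features lower in UV in blue. The bars reach 546 and 283 at 2 h, 1012 and 498 at 8 h and 464 and 402 at 12 h, with 0 at 1 h and 4 h.

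At 12 h, RGP (2.34 ± 0.27, n = 4, 5.06-fold, adjusted p = 0.000607), the chitinase (2.31 ± 0.43, 4.96-fold, adjusted p = 0.00816) and the catalase (1.46 ± 0.26, adjusted p = 0.00663) were again among the largest rises. PER42 rose by 1.29 ± 0.18 (adjusted p = 0.00184), pdi2 by 1.22 ± 0.22 (adjusted p = 0.00696) and ypt1 by 1.20 ± 0.26 (adjusted p = 0.018). Among the falls, the sucrose phosphate synthase gene sps1 changed by -0.88 ± 0.15 (adjusted p = 0.00553), Lhcb5-2 by -0.87 ± 0.16 (adjusted p = 0.00845), and pdk1, for the pyruvate phosphate dikinase of the C4 cycle, by -0.71 ± 0.14 (adjusted p = 0.00925). Further falls were those of lim1 (-0.75 ± 0.20, adjusted p = 0.0416), pOMT1 (-0.73 ± 0.18, adjusted p = 0.0345) and the receptor kinase gene ltk1 (-0.70 ± 0.17, adjusted p = 0.0315). All 12 features had one sign on 4 of 4 slides, as the naming rule required.

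Among list members at 12 h, hsp70-4 rose (0.51 ± 0.13, adjusted p = 0.0367), and a further catalase gene, cat2 (-0.67 ± 0.14, adjusted p = 0.0152), and opr6 (-0.53 ± 0.12, adjusted p = 0.022) fell, each on 4 of 4 slides. The feature of lim1 was dimmer than the brightest foreign spot. Of 20021 features, 464 rose and 402 fell. The 866 calls became 272, 224, 154 and 237 without slides a, b, c and d in turn, 427 with median centring, 482 without the dye term, 2024 with slide weights, 105 with the 12 h slides alone and 29 without the pairing. Of the 15 named results, RGP, PER42 and sps1 passed in every setting that kept the pairing, and the call of the chitinase was lost without slide c or d at a similar size (2.15 ± 0.51, adjusted p = 0.0642, and 2.22 ± 0.51, adjusted p = 0.0501). The calls of ypt1, lim1, pOMT1, ltk1 and cat2 were lost without each of the 4 slides in turn. The change of lim1 stood at -0.46 ± 0.19 without slide b (adjusted p = 0.232), while that of ypt1 stayed between 1.12 and 1.30.

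Features that share a gene symbol often differed, so the values above belong to the named features. The other catalase feature (AI491472) stood at -0.62 at 2 h, and the other RGP feature (AI396236) at 0.39 at 2 h and -0.12 at 12 h. At 8 h, further features of OBF1 (0.32), SE1B (0.38 and 0.17) and the catalase (-0.4) stood the other way. Further lim1 features stood at 0.34, 0.61, 0.018 and -0.11 at 12 h, and gpa1 features at 0.15 and -0.0044 in the mean. Further features of pdi2 (0.76 and 0.03), pdk1 (-0.35) and ltk1 (-0.64) went the same way at 12 h. The other features of arpp2a ran from -0.95 to 0.69 at 2 h. Over 979 pairs of features of one gene, the mean changes over times correlated at r = 0.273 across pairs, which are not independent, and the highest of 1000 permuted values was 0.1.

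At 1 h, no feature passed (0 of 20021 by limma; 1566 at an unadjusted p under 0.05; smallest adjusted p = 0.290). The chromatin genes nfa103 (0.63 ± 0.13, adjusted p = 0.365, higher on 4 of 4 slides) and nfa104 (0.52 ± 0.13, adjusted p = 0.415, 4 of 4) and the alcohol dehydrogenase gene adh1 (0.53 ± 0.13, adjusted p = 0.415, 4 of 4) had the smallest p among informatively named features higher in UV. Those lower in UV were ATP-D (-0.39 ± 0.092, adjusted p = 0.397, 4 of 4), wc1 (-0.87 ± 0.23, adjusted p = 0.462, 3 of 3) and the profilin gene prf1 (-1.24 ± 0.35, adjusted p = 0.492, 3 of 4). The count was 3 without slide a, 3 without slide b, 1 with median centring and 3 with loess within blocks. The slides of opposite dye assignment correlated at a median r of -0.244 across features.

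At 4 h, no feature passed either (0 of 20021 by limma; 968 at an unadjusted p under 0.05; smallest adjusted p = 0.313), and the count was 0 in every setting. The 3 named features higher in UV with the smallest p were grp1 (0.59 ± 0.12, adjusted p = 0.433, 4 of 4 slides), Pti1d (0.89 ± 0.22, adjusted p = 0.492, 3 of 3) and brd103 (0.45 ± 0.12, adjusted p = 0.628, 3 of 4). The 3 lower ones were GIF3 (-0.61 ± 0.13, adjusted p = 0.433, 4 of 4), the glutathione S-transferase gene gst41 (-1.11 ± 0.27, adjusted p = 0.492, 3 of 4) and sum1 (-0.59 ± 0.14, adjusted p = 0.492, 4 of 4). Of these, brd103 lay above the brightest foreign spot and the other 5 below it. The slides of opposite dye assignment correlated at a median r of -0.272.

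The next comparison asked whether the UV response itself differed between the times. RGP differed (adjusted p = 0.036), with changes of -0.26 ± 0.27, 1.34 ± 0.31, 0.26 ± 0.27, 1.90 ± 0.27 and 2.34 ± 0.27 at 1, 2, 4, 8 and 12 h, and positive on all 11 slides of 2, 8 and 12 h. The hypersensitive-induced reaction gene hir3 (BQ134598, adjusted p = 0.0434) stood at -0.39 ± 0.13 at 1 h, 0.73 ± 0.13 at 8 h and 0.68 ± 0.13 at 12 h. The GTPase gene ypt1 (adjusted p = 0.0434) stood at 0.57 ± 0.26, -1.21 ± 0.30, -0.23 ± 0.26, -0.94 ± 0.26 and 1.20 ± 0.26, with one sign on every slide at 2, 8 and 12 h. The ribosomal gene arpp2a (BU093490, adjusted p = 0.0434) stood at 1.42 ± 0.18 at 2 h, 0.76 ± 0.16 at 8 h and 0.02 ± 0.16 at 12 h. A further feature of hir3 (BQ294446) and one of arpp2a (AI461569) did not pass (adjusted p = 0.0521 each).

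In all, 31 of 20021 features differed in response between times, and 3056 had an unadjusted p under 0.05. With 1 slide left out, the count ran from 0 without slide c of 12 h to 257 without slide c of 2 h. It was 307 with median centring and 314 with matrix values. Each of the 4 named calls was lost in 12 to 17 of 31 settings that kept the pairing, and 1 feature passed without it. For the catalase (adjusted p = 0.0744) and the chitinase (adjusted p = 0.0534), the difference between times did not pass, so their lack of a call at 1 h and 4 h is not a tested difference.

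The calls of different times overlapped. Each time had its own slides and controls, though the dyes were assigned alike. All times shared a single fit, with the same spread and dye term per feature. Features of small spread can therefore pass at several times, so the values for independent lists are not a strict baseline. Of the features that rose at 2 h, 313 also rose at 8 h (27.6 for independent lists), and 105 fell at both (7.04). At 8 h and 12 h, 272 rose at both (23.5) and 78 fell at both (10), while 9 features went opposite ways. At 2 h and 12 h, 130 rose at both (12.7) and 45 fell at both (5.68), while 9, among them ypt1, went opposite ways. Across features, which are not independent replicates, the changes correlated at r = 0.545 between 2 h and 8 h, 0.373 between 4 h and 8 h, 0.222 between 1 h and 12 h, 0.209 between 2 h and 4 h, 0.185 between 8 h and 12 h and 0.126 between 2 h and 12 h. The other 4 pairs of times lay between -0.113 and -0.050. These values come from the fit with its dye term. Without it, the correlations lay mostly within one dye assignment. Between 2 h and 8 h, they were 0.417 and 0.437 for slides of the same assignment and 0.0632 and 0.0507 for opposite ones. Between 4 h and 8 h they were 0.454 and 0.218 against -0.0467 and -0.0952, and between 2 h and 4 h 0.599 and 0.511 against -0.419 and -0.437. Between 8 h and 12 h they were 0.16 and 0.43 against -0.123 and 0.109, between 2 h and 12 h 0.189 and 0.401 against -0.264 and -0.117, and between 1 h and 12 h 0.212 and 0.227 against 0.0284 and -0.062.

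The control samples alone were then compared between the times. Each time had its own slides, so a change in the plants cannot be told apart from a difference between slides or hybridizations. The channel medians also differed between the times. MNB1b was higher than at 1 h by 0.96 ± 0.20 at 8 h and 1.60 ± 0.20 at 12 h (adjusted p = 1.41e-05), and the phosphofructokinase gene pfk1 by 0.61 ± 0.18 and 1.16 ± 0.18 (adjusted p = 0.000159). Feature BE012178 of gpi, listed with the glycolysis genes, rose by 1.56 ± 0.33 at 8 h and 1.70 ± 0.33 at 12 h (adjusted p = 0.00341), and sps1 by 1.07 ± 0.26 and 1.19 ± 0.26 (adjusted p = 0.00508). PUMP, named for a mitochondrial uncoupling protein, stood at 0.69 ± 0.14 at 12 h (adjusted p = 0.00175), and the GTPase gene yptm3 at 0.86 ± 0.19 at 4 h and 1.03 ± 0.19 at 12 h (adjusted p = 0.00339). These 6 passed in all 30 settings that kept the pairing.

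Of 14234 features, 1964 differed between times in controls, and 4513 had an unadjusted p under 0.05. Against 1 h, 0 features were higher and 1 lower at 2 h (1486 at an unadjusted p under 0.05), 872 higher and 1073 lower at 4 h, 39 and 34 at 8 h, and 344 and 253 at 12 h. The count became 596, 614 and 782 without slides d, c and b of 4 h, 3641 without slide a of 4 h, 1151 without slide c of 12 h, 1298 without slide c of 1 h and 2953 without slide d of 2 h. 

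**Figure D3:**
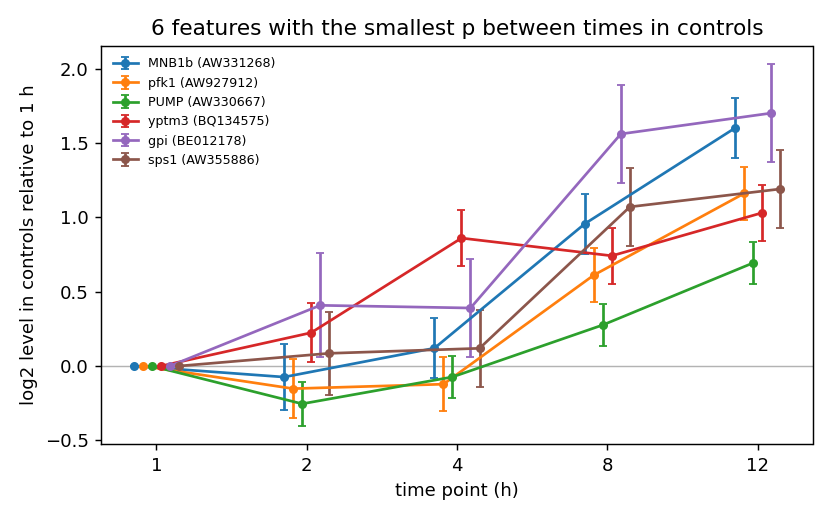
Level in control plants relative to 1 h (vertical axis, log2 units) against the time in h (horizontal axis, evenly spaced) for the 6 named features with the smallest p between times; points are fitted differences and bars are SE. At 12 h, gpi stood at 1.70, MNB1b at 1.60 and PUMP at 0.69.

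The gene lists fixed in advance had few members on the slides, and in the mean over times the members of most went both ways. Of 35 antioxidant and detoxification features, 6 rose and 2 fell (9 and 2 adjusted over the list alone), the catalase, sod3 (0.22 ± 0.047, adjusted p = 0.00519) and 3 glutathione S-transferase features among the risers, and cat2 (-0.34 ± 0.065, adjusted p = 0.00278) and fsd1 (-0.20 ± 0.047, adjusted p = 0.0104) as those that fell. Of 12 jasmonate and lipid signalling features, 2 rose and 1 fell (3 and 1 adjusted over the list alone), with opr1 at 0.45 ± 0.087 (adjusted p = 0.00286) and opr6 at -0.29 ± 0.057 (adjusted p = 0.00359). Of 12 heat shock and chaperone features, 2 rose and 0 fell, adjusted over the list alone likewise, both of hsp70-4. Of 32 histone and chromatin features, 2 rose and 2 fell (3 and 4 adjusted over the list alone), among them nfc102 (0.50 ± 0.11, adjusted p = 0.00838).

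Of 22 sugar and starch features, 2 rose and 2 fell, adjusted over the list alone likewise, with sh2 at 0.21 ± 0.041 (adjusted p = 0.00281). Of 35 features for dividing cells, 2 rose and 1 fell (1 and 1 adjusted over the list alone), and of 7 endosperm and seed storage features, 0 rose and 2 fell, adjusted over the list alone likewise, both of glb1. None of these 7 lists passed the camera test at any time or in the mean (smallest adjusted p = 0.615, endosperm and seed storage). The other 6 lists held under 5 features and were not tested as lists. The photosynthetic light reactions had 2, of which psbs1 feature AW129847 fell (-0.29 ± 0.073, adjusted p = 0.0145), and 1 rose and 1 fell adjusted over the list alone. Of 3 mesophyll C4 cycle features, pdk1 fell (2 fell adjusted over the list alone), and of 3 bundle sheath features, rbcs1 (-0.37 ± 0.11, adjusted p = 0.0284) and rca1 (-0.25 ± 0.067, adjusted p = 0.0204) fell, adjusted over the list alone likewise. The chitinase rose (1.17 ± 0.20, adjusted p = 0.00114) as 1 of 2 pathogenesis-related and wound features, adjusted over the list alone likewise. None of the 4 flavonoid and phenylpropanoid features passed (0 adjusted over the list alone), and the 1 root feature, zrp4, rose by 0.22 ± 0.063 (adjusted p = 0.0334, likewise adjusted over the list alone).

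Of the 22 lists built from the symbols on the slides, 7 passed in the mean over times with the preset correlation and none with an estimated one, and most of their members did not pass singly. Of 35 features for protein folding in the endoplasmic reticulum, 13 rose and 0 fell in the mean over times (median 0.13, higher on 17 of 19 slides, adjusted p = 4.87e-05, adjusted p = 0.175 with an estimated correlation), among them CNX, crt2, pdi2 and the disulfide isomerase feature pdi AW147172 (0.41 ± 0.073). Of 34 translation factor features, 12 rose and 1 fell (median 0.10, higher on 14 slides, adjusted p = 0.00103, adjusted p = 0.251 with an estimated correlation), with elfa3 feature BQ401279 at 0.36 ± 0.044 and eIF4E1 feature AW506733 as the one that fell, at -0.34 ± 0.10. Of 37 ribosomal protein features, 11 rose and 0 fell (median 0.056, higher on 17 slides, adjusted p = 0.00548, adjusted p = 0.265 with an estimated correlation), with rpl17 feature AI714634 at 0.45 ± 0.053. Of 24 cystatin and pathogenesis-related features, 6 rose and 0 fell (median 0.076, higher on 15 slides, adjusted p = 0.0114, adjusted p = 0.175 with an estimated correlation), with the chitinase and the cystatin genes cc4 (0.41 ± 0.086) and cc10 (0.32 ± 0.068) among them.

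The photosynthesis list stood lower. Of its 37 features, 0 rose and 15 fell in the mean over times (median -0.15, lower on 17 of 19 slides, adjusted p = 0.00258, adjusted p = 0.322 with an estimated correlation). Besides gpa1, Lhcb5-2 and pdk1, they included lhcb5 (AW927758, -0.37 ± 0.067), the ferredoxin reductase gene L-FNRI (-0.32 ± 0.077) and pgr5 (-0.29 ± 0.054), named for proton gradient regulation. At 12 h, 8 of them fell (median -0.20, 4 of 4 slides, adjusted p = 7.03e-05, adjusted p = 0.251 with an estimated correlation). Cell wall features went both ways, with 4 rising, RGP and HRGP among them, and 7 falling, CesA-9, cesa5 and lop1 among them (46 features, median -0.12, lower on 17 slides, adjusted p = 0.0342, adjusted p = 0.175 with an estimated correlation).

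By time, 4 of the same lists passed with the preset correlation at 2 h. Translation factors (7 rose, median 0.29, adjusted p = 4.56e-05, adjusted p = 0.175 with an estimated correlation) and endoplasmic reticulum folding (5 rose, median 0.27, adjusted p = 0.000187, adjusted p = 0.225 with an estimated correlation) stood higher. So did ribosomal proteins (5 rose, median 0.19, adjusted p = 0.0306, adjusted p = 0.415 with an estimated correlation). Photosynthesis stood lower (median -0.15, adjusted p = 0.0342, adjusted p = 0.499 with an estimated correlation). At 8 h, cystatins and pathogenesis-related genes (5 rose, median 0.16, adjusted p = 0.00609, adjusted p = 0.175 with an estimated correlation) passed. Translation factors also passed (6 rose, median 0.21, adjusted p = 0.0114, adjusted p = 0.322 with an estimated correlation). Endoplasmic reticulum folding passed with 1 riser (median 0.19, adjusted p = 0.0155, adjusted p = 0.366 with an estimated correlation). Photosynthesis (2 rose, 3 fell, median -0.19, adjusted p = 0.0306, adjusted p = 0.499 with an estimated correlation) was lower at that time. The cell wall list was lower too (3 rose, 4 fell, median -0.18, adjusted p = 0.0306, adjusted p = 0.175 with an estimated correlation). Ribosomal proteins were higher (6 rose, median 0.17, adjusted p = 0.0373, adjusted p = 0.456 with an estimated correlation). At 12 h, ribosomal proteins (3 rose, median 0.18, adjusted p = 0.00163, adjusted p = 0.251 with an estimated correlation) and endoplasmic reticulum folding (6 rose, median 0.096, adjusted p = 0.00387, adjusted p = 0.259 with an estimated correlation) passed. Translation factors (1 rose, median 0.17, adjusted p = 0.0223, adjusted p = 0.389 with an estimated correlation) remained higher. Cystatins did likewise (2 rose, median 0.14, adjusted p = 0.0342, adjusted p = 0.175 with an estimated correlation). At these 3 times, the list median had one sign on every slide. At 1 h, where no single feature passed, photosynthesis (median -0.098, adjusted p = 0.0114, adjusted p = 0.415 with an estimated correlation) and endoplasmic reticulum folding (median 0.14, adjusted p = 0.0306, adjusted p = 0.429 with an estimated correlation) passed. No list of either family passed at any time with an estimated correlation.

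**Figure D4:**
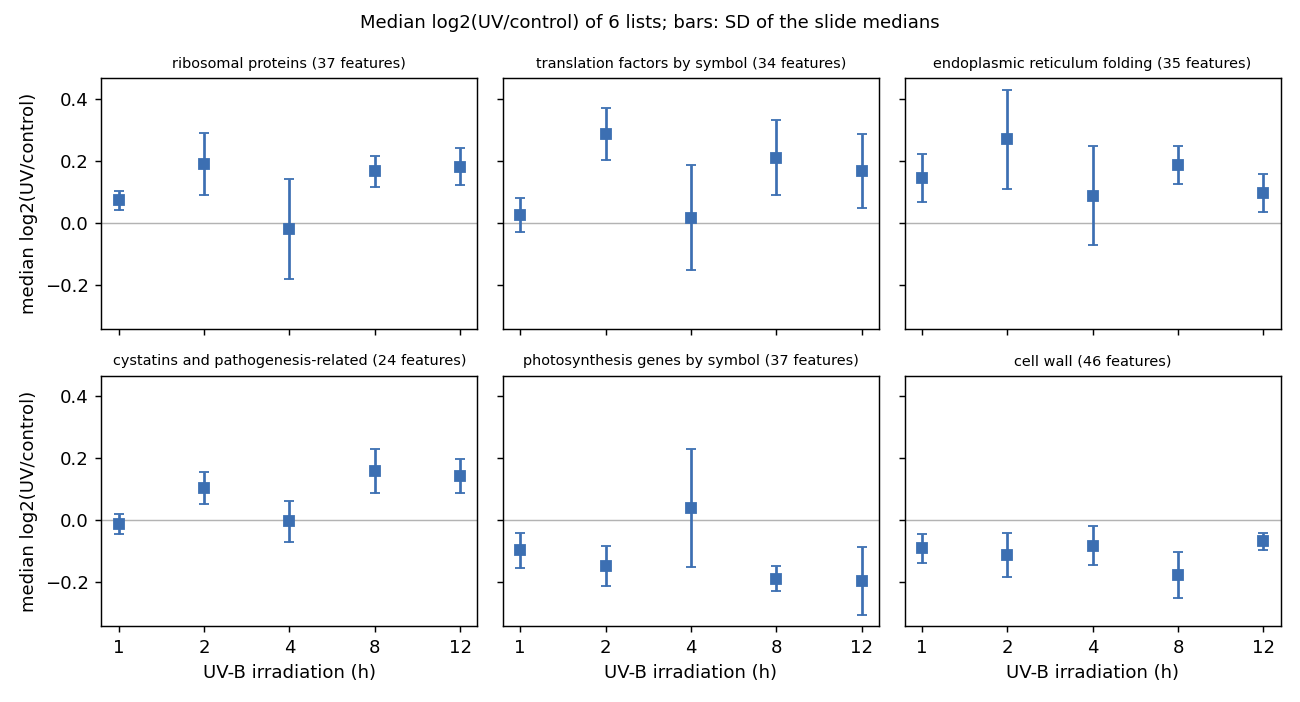
Median log2(UV/control) of the features of 6 lists (vertical axes, log2 units) against the duration of UV-B in h (horizontal axes, evenly spaced); squares are medians of the fitted changes over the features and bars are the SD of the slide medians. The photosynthesis list stood at -0.20 at 12 h and the translation factors at 0.29 at 2 h.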

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

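The tests of spread and of a smaller change at 4 h, the dye tests and the test of displaced names below were chosen after the results they bear on had been seen. Groups of 4 slides or samples were searched for a value far from the others, and 7 of 90 groups held one; chance alone gives about 1 in 20 groups. At 4 h, slide b held 18795 spots in both channels, UV and control, against 19974 to 20158 on the others. The log2 ratios of slide a at 4 h had an SD of 0.6036, against 0.4223 to 0.4443. The median of the histone and chromatin list was 0.139 on slide c at 4 h, against -0.025 to 0.0016, and that of the jasmonate and lipid list was 0.0524 on slide a at 4 h, against -0.037 to -0.023. At 8 h, aoc1 (BQ294408) stood at 2.44 on slide a, against 0.49 to 0.59. At 12 h, lim1 stood at -1.41 on slide b, against -0.62 to -0.46.

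The UV response differed between the times for 31 features by the F-test, among them RGP (adjusted p = 0.036) and, at adjusted p = 0.0434 each, hir3 (BQ134598), ypt1 and arpp2a (BU093490). The adjusted p over the settings ran from 0.00618 to 0.132 for RGP, from 0.0101 to 0.132 for hir3, from 0.00752 to 0.136 for ypt1 and from 0.0235 to 0.135 for arpp2a. The median of the heat shock and chaperone list was above 0 on every slide at 1 h and below 0 on every slide at 4 h, a difference of -0.175 that was not tested.

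No feature passed at 4 h although 829 passed at 2 h and 1510 at 8 h. A larger spread at 4 h was tested by the residual SD, which was 0.335 on average over the 4 h slides, against 0.430 at 2 h and 0.337 at 8 h, and so was not larger. An exchange of UV and control on 1 or 2 of the 4 h slides would need many calls after turning those slides back, and the most that any such turn gave was 29. The 1510 features of 8 h had a median change of 0.0828 at 4 h in their 8 h direction, against 0.414 at 2 h, with 0.005, 0.17, 0.18 and -0.02 on slides a to d, so a smaller change in the same direction may be part of the pattern. No test compared the response at 4 h directly with that at 2 h or 8 h, so a smaller response at 4 h is itself not established. If there was one, whether UV-B had a smaller effect or the 4 h plants received less of it stays open, since the design gives no dose measure.

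Slides of opposite dye assignment correlated below 0 at 1 h (median r = -0.244), 2 h (-0.285) and 4 h (-0.272), and above 0 at 8 h (0.198) and 12 h (0.132). This was not particular to the times without a passing feature, since 829 passed at 2 h. A dye value of each feature shared by all times was tested by subtracting the value taken from the other times. At 1 h the median stayed at -0.2293, with all 4 pairs between -0.342 and -0.176, so a shared dye value alone does not account for it. At 4 h it moved to -0.1046, with pairs from -0.214 to 0.064, which leaves such a value open, and a dye value of that time alone was not tested. At 2 h it moved to -0.0686, on 2 pairs that share slide a and are too few to decide. An exchange in the labels of which dye held UV on slides c and d of 1 h gave 251 features when turned back, but a dye effect of 1 h alone would give the same, so these cannot be told apart.

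Features of one gene often differed, with a correlation of 0.273 over 979 pairs for the mean change and 0.083 for mean intensity. Noise in features that hardly changed was tested on pairs in which both passed. Of these, 88.5% (54 of 61) went the same way, against a median of 55% with genes permuted over features (permutation p = 0.001). The share lay between the limits set for the test, so noise as the whole source stays open. Names displaced by a few positions could lower the correlation, but the highest over 48 displacements was 0.145, against 0.267 at the stated positions for 998 pairs of spots. Features at 2 positions correlated at 0.080 in mean change and at -0.254 in mean intensity (35 features). Whether each identifier belongs to its position in all blocks of spots therefore stays open, which bears on every named value, and no biological explanation, such as related gene copies on one symbol, was tested.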

How the results depend on the processing

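The loess within blocks of spots, the filter at the brightest foreign spot and the offset without normexp were chosen after seeing the data. Without the replicate block, that is with UV and control of a slide taken as unpaired, the counts were 0 at 2 h, 9 at 8 h, 29 at 12 h, 132 for the mean over times and 1 between times, against 829, 1510, 866, 2884 and 31, and the control time course gave 1686 against 1964. Without the dye term they were 420 at 2 h, 893 at 8 h, 482 at 12 h and 3 between times. With median centring they were 1 at 1 h, 3183 at 8 h, 427 at 12 h and 307 between times, and 47.3% of the calls at 8 h were higher in UV, against 67%. Between times, the count was 130 without background correction, 130 with the offset alone, 181 without the dimmest features, 183 above the foreign spots, 314 with matrix values, 104 with trend and robust variances, 15 with slide weights and 76 with loess within blocks. At 2 h it was 1270 without the dimmest features, 1273 above the foreign spots, 1671 with matrix values, 392 with slide weights (77.3% higher, against 65.9%) and 43 after scaling (93% higher), and at 1 h it was 3 with loess within blocks. With slide weights 2723 passed at 8 h and 2024 at 12 h, and after scaling 986 passed at 8 h. With matrix values 65.3% of the calls at 12 h were higher, against 53.6%. With the slides of a time fitted alone, 0 passed at 2 h, 0 at 8 h and 105 at 12 h. Leaving out 1 slide gave 0 to 3 at 1 h, 203 to 938 at 2 h, 0 at 4 h, 7 to 1851 at 8 h, 154 to 929 at 12 h, 2180 to 2910 for the mean over times, 0 to 257 between times and 596 to 3641 in controls. At 4 h the count was 0 throughout. The fits to a time alone rest on fewer slides and also had no dye term, and which of these lowered their counts was not tested. For the other settings the cause was not tested either. In the settings that kept the pairing, 2283 values of named features were compared, and the fit without it is left out of these totals. Of these values, 2016 kept direction and side of the threshold, 265 kept direction and lost the call, and 2 reversed. Both reversals came with median centring: glb1 (AW066754) at 8 h stood at -0.161 and brd103 (AW225035) at 4 h, which had no call, at -0.0858. The cause of these reversals was not tested. The values that kept their side include features of 1 h and 4 h, which had no call to lose, and fits without a slide of another time. The naming rule also favoured features of one direction, so the kept directions are not separate evidence. Fewer calls held whichever slide of their own time was left out. These were 2 of 14 named results at 2 h, 0 of 20 at 8 h and 4 of 15 at 12 h. Also with the pairing kept, 285 of 365 values of the named tests between times kept their side, 60 lost the call and 20 gained it. Of 5539 list medians in these settings, 212 moved by more than the spread between slides. Medians of lists that passed the camera test kept their sign, while others did not, as that of the jasmonate and lipid list at 1 h, which took the other sign in 15 of 32 settings, and that of DNA replication at 12 h, which went from 0.0827 to -0.264 in 1. The signal over background limits the features dimmer than the brightest foreign spot; with 14512 features above it, 1564 passed at 8 h and 1126 at 12 h.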

Other observations

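The tests of opposite direction were recast on all features after their values had been seen, and the lists were built from the symbols on the slides before any expression value was seen. Some members of groups outside the main comparisons passed in the mean over times. Of 30 glycolysis and fermentation features, 9 rose and 3 fell; the risers included 5 features of the enolase gene eno1 (0.24 to 0.33), and those that fell were pfk1 (-0.19 ± 0.043) and 2 features of gpi (-0.25 ± 0.047 and -0.18 ± 0.052). This list passed at 2 h (median 0.26, 2 rose, adjusted p = 0.025, adjusted p = 0.258 with an estimated correlation). Of 23 features for enzymes of reactive oxygen, 6 rose, with the thioredoxin gene trh2 (0.43 ± 0.055) beside the catalase and PER42, and 2 fell, cat2 and the iron superoxide dismutase gene fsd1. That list passed at 2 h (median 0.23, 3 rose, adjusted p = 0.0342, adjusted p = 0.175 with an estimated correlation). The 3 features of MMT1, a methionine methyltransferase gene, that rose stood between 0.36 and 0.38 in the nitrogen and sulfur list, where 5 of 33 features rose and 2 fell (adjusted p = 0.714). Of 39 pollen and flower features, markers of other organs, 1 rose and 4 fell (median -0.13, lower on 15 of 19 slides, adjusted p = 0.0443, adjusted p = 0.256 with an estimated correlation), 3 of the 4 being features of lop1, which the cell wall list also holds. It also passed at 8 h (1 rose, 5 fell, median -0.12, lower on 4 of 4 slides, adjusted p = 0.0283, adjusted p = 0.237 with an estimated correlation).

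The other lists built from symbols did not pass in the mean over times, by the camera test of limma. Of 32 aquaporin features 5 rose and 0 fell (adjusted p = 0.998), of 91 chromatin features 9 rose and 4 fell (0.971), of 24 glutathione S-transferase features 3 rose and 0 fell (0.264), and of 38 sucrose and starch features 2 rose and 5 fell (0.466). Of 13 jasmonate synthesis features 2 rose and 1 fell (0.737), of 14 heat shock features 2 rose and 0 fell (0.972), of 12 DNA replication features 1 rose and 0 fell (0.972), and of 59 cytoskeleton features 1 rose and 1 fell (0.953). Of 10 dehydration and cold features 0 rose and 2 fell (0.972), of 17 two-component features 1 rose and 0 fell (0.998), of 16 endosperm and embryo features 0 rose and 3 fell (0.737), and of 9 phenylpropanoid and flavonoid features none passed (0.804).

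The counts were repeated with UV and control turned on other sets of slides. For the mean over times, 1 of 100 draws, the real one, gave as many features (2884), the smallest share that 100 draws can give. The draws took the slides as separate units, which the labels do not settle. The highest other draw gave 2693, with 16 of 19 slides kept one way, and the next gave 71. Another draw with 16 slides kept gave 0 and one with 17 gave 8, so closeness to the real assignment alone does not account for the 2693. Between times, with the times of the slides permuted, 1 of 100 draws gave as many as 31, the highest other being 2. For controls 1 of 100 gave as many as 1964, the highest other being 1444. Such counts were thus rare among the draws, if the slides are separate units. Leaving out a single slide brought the real counts as low as 0 between times and 596 in controls. What raised the 1444 of a permuted draw was not examined. At single times the splits are too few for a share under 0.05: at 2 h, 1 of 4 gave as many as 829 (highest other 24), at 8 h 1 of 8 gave as many as 1510 (highest other 0), at 12 h 1 of 8 gave as many as 866 (highest other 1), and at 1 h and 4 h all 8 splits gave at least the real count of 0 (highest others 251 and 29).

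A hypothesis was that UV-B opposes the changes that control plants undergo over the hours. It was tested with the control change taken from slides a and b and the UV response from slides c and d, or the reverse. The test was first run on the 1964 features that differed between times in controls, with a limit of -0.1, and gave correlations of -0.164 and -0.125 at 12 h and -0.0563 and 0.179 at 8 h. These features were chosen partly on the control samples that also enter the UV response, which by itself favours values below 0, so the values at 12 h decide nothing. The test was therefore recast on all 14234 features measured on all slides. At 8 h, the correlations were then 0.000618 and 0.197, neither below 0. The UV response was not corrected for dye here, and the controls of one slide pair carried the same dye as the UV samples of the other. A dye value that differs between times would therefore raise the values at both times, so those of 8 h do not decide the question. At 12 h, they were -0.0716 and -0.084, short of the limit, so the hypothesis stays open for that time. If slides of opposite dye assignment shared control plants, which the labels do not say, that alone would lower these values.

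The foreign spots had a median log2(UV/control) of -1.21 on slide b of 8 h, -1 on slide a of 2 h, -0.95 on slide a of 8 h and 0.51 on slide c of 1 h, and between -0.42 and 0.23 on the others. On the 3 slides furthest below 0, UV was in Cy5.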
